A study of Mus musculus with 6 samples.

How the data were processed

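Total RNA from homogenised calvaria of newborn mice was sequenced after a stranded messenger RNA library preparation, per the labels' protocols. The 6 libraries fall into 3 controls with floxed alleles of Pth1r and 3 labelled mutant that also carry Prx1-Cre, and both the group and the replicate number come from the sample titles. The files hold 1 table per library with a gene name and a value for each of 24346 names. The deposited values are FPKM, as made by the authors with Cufflinks, and they were used as deposited. Per the submitters' processing notes, the tools were TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19 and Cufflinks 2.2.1, with the mm10 build. Their options, the gene annotation, the use of strand and the read totals were not given in the sources used here. Plain FPKM scales each gene by its length and each library by its total, so a few abundant genes can shift the rest. Whether the values were further normalized between libraries was not given in the sources used here. Their median-of-ratios factors ran only from 0.999 to 1.01. Cufflinks divides ambiguous fragments between overlapping or near-identical genes by a model. Very short genes receive unstable FPKM values, and short RNA genes are therefore uncertain. The 10 most abundant genes took between 11.3% and 13.8% of the summed FPKM of a library.

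Because absolute depth is unknown, relative depth was read from genes under 0.05 FPKM in both of 2 libraries, where the ratio of values peaks at the ratio of what 1 fragment is worth. Between 43.7% and 47.8% of such genes lay within 2% of the peak, and 23.6% to 27.5% at ratios of 2 to 1 or 1 to 2 around it. The values could not be turned into whole reads, since gene lengths enter them, so no test for counts was run. Precision was judged from the spread between libraries. Correlations of log2 values between libraries ran from 0.971 to 0.979 within groups and from 0.967 to 0.977 between groups.

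Genes with a mean of at least 1 FPKM over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend), with group as the 1 term, two-sided, and Benjamini-Hochberg adjustment over 13180 genes at 0.05. Log2 changes are on the log2(FPKM + 1) scale, which understates changes of low genes, while ratios and fold values are of group means of FPKM. The 31 gene lists, the test, the rule for named genes and most of the other settings tried were set before the data were examined. The lists were written by hand, and 4 of their 490 entries matched no name. The 30 lists with at least 5 measured members were tested with limma's camera at a preset correlation of 0.01, with adjustment over the lists. Camera was repeated with an estimated correlation, which left 0 lists past the threshold (3 at an unadjusted p under 0.05), and fry, which tests whether the members of a list move on balance in 1 direction, called 3. Targeted Pth1r was also tested by exact permutation.

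The procedure was tested on simulated data drawn from the means and spreads of the 13180 genes, with 200 genes changed in each of 10 simulations. It recovered 61.2% of genes changed 1.5-fold, 85.4% of those changed 2-fold and 96.7% of those changed 4-fold, and 4.59% of its calls were false. These folds are of FPKM + 1, so for low genes the simulated change of FPKM itself was larger than the fold given. A planted list was called in 10 of 10 simulations and 0 of 20 unchanged lists were called. Simulated genes were independent, so list calls under correlation between genes were not tested.

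The genes named in the text follow a rule fixed in advance. They are Pth1r, then the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, then in each described list the 3 members with the smallest p and any member past the threshold, and for lists of other cell types and quality also the 2 most abundant. Lists are described gene by gene where they passed, where a member passed, or where they stand for muscle, red cells, neural tissue, sex or handling, a choice partly made after seeing the data. Other genes are marked as named after their values were seen. Gene coordinates come from GENCODE M21 on GRCm38, the assembly that mm10 denotes. Of the tested names, 12730 matched it by symbol and 392 by an older symbol listed in a RefSeq gene table, and 58 did not match.

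The other settings chosen then were a pseudocount of 0.1, no filter on low values, a filter at a mean of 5 FPKM, median-of-ratios scaling, quantile normalization, eBayes without trend, robust eBayes, array weights, the replicate number as a block, and leaving out each library. A sex term, read from Xist and the Y-linked genes, and a fit without short RNA genes were chosen after seeing the data. Robust eBayes has no counterpart in camera, so it gives no list result. No library was left out of the main comparison.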

Results

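The calvaria is the roof of the skull, made of flat bones, the sutures that join them and the cartilage that lies beside them. It was dissected from newborn mice, and its messenger RNA was sequenced. Per the labels, the interparietal and occipital bones were kept and the cartilage of the ears was left out. Of the 6 libraries, 3 came from control animals with floxed alleles of Pth1r and 3 were labelled mutant, with the same alleles and the Prx1-Cre transgene, which is known to recombine floxed alleles in mesenchyme of the limbs and skull. Pth1r encodes the receptor shared by parathyroid hormone and parathyroid hormone-related protein. Each library gave FPKM values (fragments scaled to transcript length and to the library's mapped fragments) for 24346 gene names, and the 13180 names with a mean of at least 1 FPKM were tested. Read totals were not given in the sources used here, so absolute depth is unknown. The smallest values fall on steps set by single fragments, and with control 1 set to 1 these gave a relative depth of 0.845 in control 2, 0.914 in control 3, and 0.97, 0.778 and 0.703 in libraries 1 to 3 labelled mutant. The title of the series names the question, which is how signalling through this receptor bears on skull cartilage, the forming sutures and their early fusion, called craniosynostosis.

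Pth1r, the targeted gene, was not lower in the libraries labelled mutant. Its value was 89.2, 93.3 and 102 FPKM in the control libraries and 127, 125 and 142 FPKM in those labelled mutant. The means were 94.8 ± 6.55 (SD, n = 3) and 131 ± 9.45 (SD, n = 3), a ratio of 1.38. The log2 difference of 0.47 ± 0.08 (SE) did not pass the threshold in limma with Benjamini-Hochberg adjustment (adjusted p = 0.065). An exact permutation test of the means, two-sided, gave p = 0.1, the smallest p that 3 values against 3 allow. The gene spans positions 110722085 to 110747145 of chromosome 9 on the minus strand of GRCm38, and its span overlaps Myl3 on the plus strand. Which exons the floxed alleles remove was not given in the sources used here, and a value for the whole gene can include reads from exons that remain. Because the targeted gene goes against the labels, each direction below is that of the labels alone.

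In the libraries labelled mutant, genes of osteoclasts, the cells that resorb bone, were higher, and genes of cartilage matrix were lower. As lists, both passed in camera with a preset correlation and neither did with an estimated correlation (adjusted p = 0.104 for osteoclast and 0.397 for cartilage matrix). In fry the osteoclast list passed (adjusted p = 0.00164) and the cartilage matrix list did not (adjusted p = 0.0682). The osteoclast list had 9 of its 17 measured members past the threshold, all higher, and the cartilage matrix list had 6 of 27, all lower. Across all tested genes, 69 rose and 11 fell at an adjusted p of 0.05 (limma with Benjamini-Hochberg adjustment), of which 23 rises and 8 falls reached a log2 change of 1. Leaving out a short RNA gene and a gene that shares reads with near-identical copies, the largest rises were those of Mmp9, Mt3, Acp5, Ocstamp, Dcstamp, Atp6v0d2, Oscar and Mmp13, and the largest falls those of Matn1, Ucma, Col9a3, Mfi2 and Lect1. All 80 of these genes had groups that did not overlap, as did 16.1% of all tested genes, where chance gives 10% for 3 libraries against 3.

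**Figure D1:**
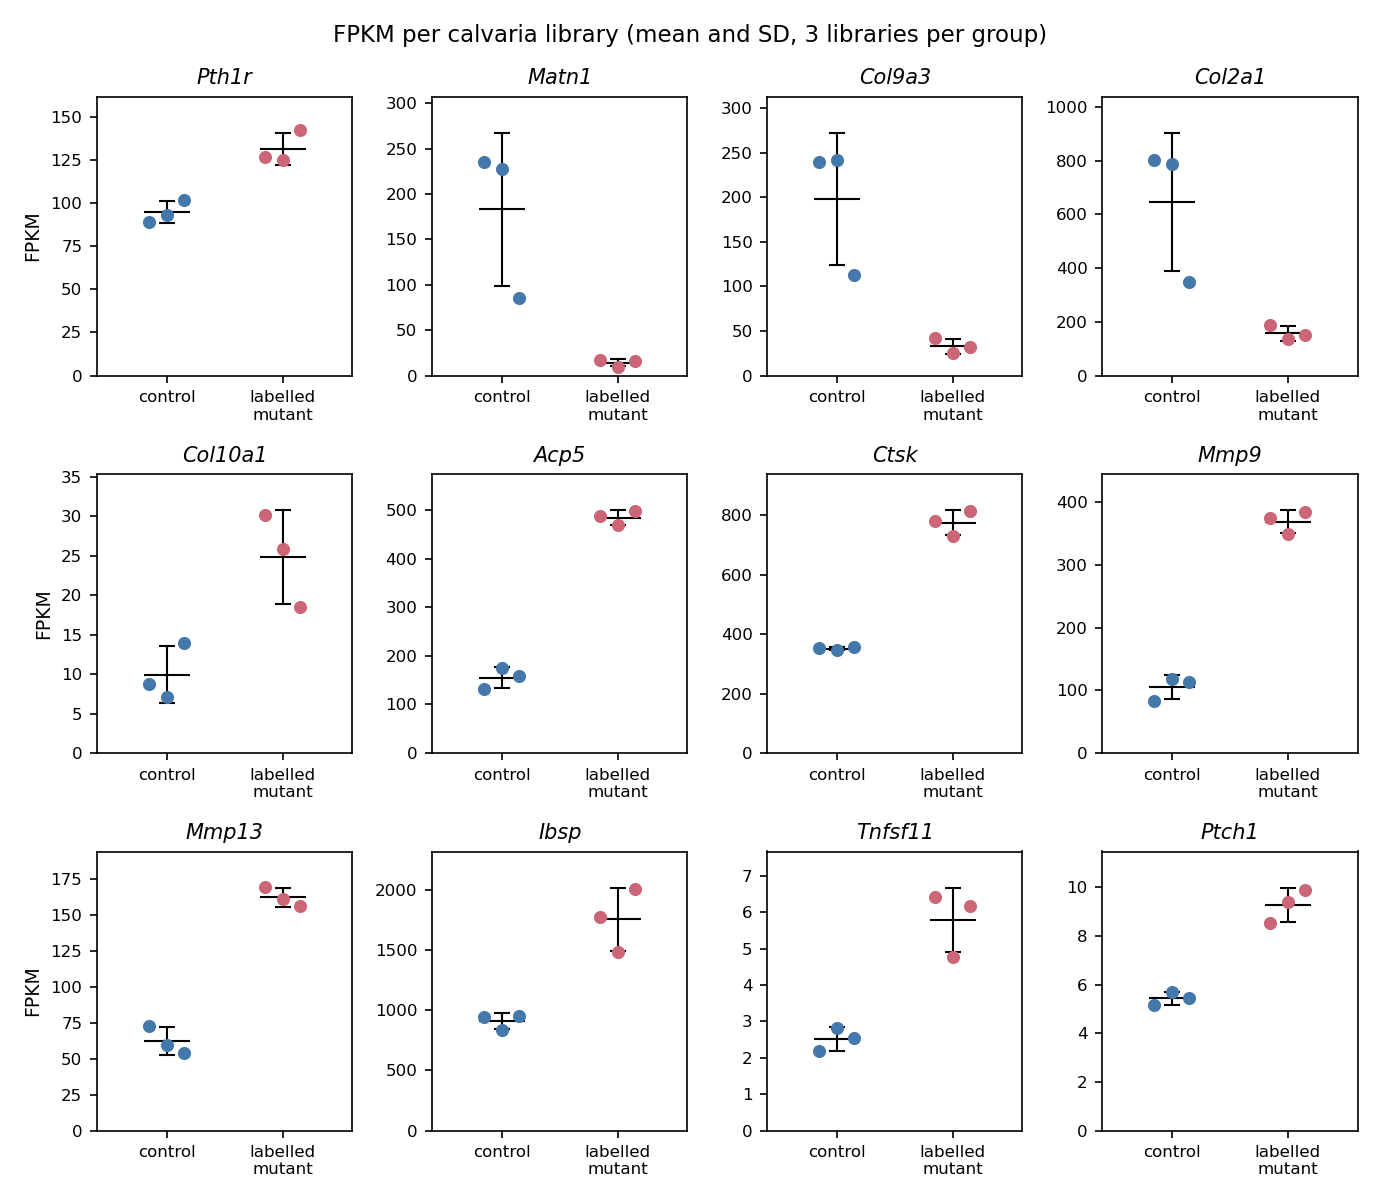
FPKM of 12 genes in each library (points), with the mean (horizontal line) and SD (bars) of 3 control libraries (blue) and 3 libraries labelled mutant (red); each vertical axis is linear and starts at 0. Pth1r lies at 125 FPKM or more in the libraries labelled mutant and at 102 FPKM or less in the controls, and control 3 has the lowest control value of Matn1 (85.7), Col9a3 (113) and Col2a1 (348).

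Cartilage matrix genes made up most of the falls. Matn1, which encodes matrilin-1 of the cartilage matrix, had 183 ± 84.4 FPKM (SD, n = 3) in controls and 14.3 ± 4.32 (SD, n = 3) in the libraries labelled mutant, 12.8-fold less, and fell by 3.50 ± 0.41 (SE) on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.0205). Ucma, made by growth cartilage, went from 36.7 ± 10.02 to 3.28 ± 1.88 FPKM (SD, n = 3 each). The collagen IX chain gene Col9a3 went from 198 ± 74.2 to 32.9 ± 8.34 FPKM (SD, n = 3 each), and Lect1, the older name of the chondromodulin gene Cnmd, from 74.0 ± 25.2 to 16.7 ± 3.16. Epyc, a small proteoglycan gene, had 2.44-fold less, and Cilp2 had the smallest p of the list, at 14.2 ± 0.25 against 5.22 ± 0.42 FPKM (SD, n = 3 each; adjusted p = 0.00112 in limma with Benjamini-Hochberg adjustment). Of the 27 measured members, 25 had a lower value and 2 a higher one, and 17 fell when adjusted over the list alone. Col2a1, the main collagen of cartilage, was singled out after its values were seen and did not pass, at 802, 788 and 348 FPKM in controls and 188, 135 and 149 FPKM in the libraries labelled mutant (limma, Benjamini-Hochberg adjusted p = 0.0638). The list lay below other genes in limma's camera with a preset correlation (median log2 change -1.01, adjusted p = 4.08e-22). It did not pass with an estimated correlation (adjusted p = 0.397) or in fry (adjusted p = 0.0682).

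Control 3 stood apart from controls 1 and 2 in this list, with a mean log2 value of 4.83 over the members against 5.47 and 5.54, and the libraries labelled mutant had 4.31, 3.91 and 4.16. Control 2 alone held 56.6 FPKM of Oc90, an otoconia gene of the inner ear, against 1.00 or less elsewhere, and 22.5 FPKM of Otor, which is known from the cochlea and is a member of the list. The number of list members that fell was 1, 1 and 8 without control 1, 2 or 3, and 1, 3 and 2 without library 1, 2 or 3 labelled mutant. With all libraries, it was 2 with robust eBayes, 1 with a sex term, 1 with the replicate number as a block, 3 with no filter on low values and 10 without short RNA genes. Cilp2 fell in each of these fits. Among the fits lacking a library, Matn1 passed only without control 3, with an adjusted p between 0.00697 and 0.0904 over all settings tried, and Col2a1 passed there too (between 0.00697 and 0.2).

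Genes of maturing, hypertrophic chondrocytes went, as a list, the other way from cartilage matrix. Mmp13, a collagenase of hypertrophic cartilage and bone, rose from 62.2 ± 9.61 to 162 ± 6.64 FPKM (SD, n = 3 each), a log2 change of 1.38 ± 0.11 (SE; adjusted p = 0.00415, limma with Benjamini-Hochberg adjustment). It was the 1 member of 9 to pass. Col10a1, the collagen that marks hypertrophic chondrocytes, had 8.73, 7.16 and 14.0 FPKM in controls and 30.2, 25.9 and 18.5 FPKM in the libraries labelled mutant without passing (adjusted p = 0.109 in limma with Benjamini-Hochberg adjustment). Cd200 had 36.8 ± 5.50 against 51.3 ± 2.47 FPKM (SD, n = 3 each) and did not pass. Of the 9 measured members, 7 had a higher value and 2 a lower one, and 3 rose when adjusted over the list alone. The list was higher in camera with a preset correlation (median log2 change 0.26, adjusted p = 0.000124) and in fry (adjusted p = 0.0177), but not with an estimated correlation (adjusted p = 0.183).

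Osteoclast genes rose the most often of any list. Acp5, which encodes tartrate-resistant acid phosphatase, rose from 155 ± 21.0 to 485 ± 14.9 FPKM (SD, n = 3 each), and Ctsk, the collagen-degrading protease cathepsin K, from 351 ± 4.64 to 775 ± 41.2. Mmp9, a gelatinase abundant in osteoclasts, rose 3.52-fold to 369 ± 17.9 FPKM (SD, n = 3), a log2 change of 1.82 ± 0.13 (SE; adjusted p = 0.00349, limma with Benjamini-Hochberg adjustment). The genes for cell fusion, Dcstamp and Ocstamp, rose 3.56-fold and 3.72-fold from low levels of 2.18 ± 0.17 and 3.17 ± 0.81 FPKM (SD, n = 3 each). Atp6v0d2 and Tcirg1, subunits of the proton pump that acidifies the resorption pit, rose 2.90-fold and 1.54-fold, and the integrin gene Itgb3 and the receptor gene Oscar rose 2.203-fold and 3.18-fold. All 17 members had a higher mean in the libraries labelled mutant, and 14 rose when adjusted over the list alone. The list was higher in camera with a preset correlation (median log2 change 0.83, adjusted p = 1.14e-27) and in fry (adjusted p = 0.00164), and its adjusted p was 0.104 with an estimated correlation. Its mean log2 value ran from 3.55 to 3.72 in controls and from 4.50 to 4.65 in the libraries labelled mutant.

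Among factors by which bone-forming cells control osteoclasts, Tnfsf11, the gene of the osteoclast-inducing ligand RANKL, rose from 2.52 ± 0.32 to 5.79 ± 0.88 FPKM (SD, n = 3 each), a log2 change of 0.94 ± 0.12 (SE; adjusted p = 0.031, limma with Benjamini-Hochberg adjustment). Among the fits lacking a library, it passed only without library 2 labelled mutant (adjusted p up to 0.131 over all settings tried). The other members did not pass. Csf1, a growth factor for osteoclast precursors, had 24.0 ± 1.31 and 29.8 ± 1.23 FPKM (SD, n = 3 each), Il34 had 4.20 ± 0.79 and 3.91 ± 0.52, and Tnfrsf11b, the RANKL decoy receptor gene, named after its values were seen, had 10.01 ± 1.88 and 9.86 ± 1.86. Adjusted over the list alone, 2 of the 6 members rose. The list did not pass in camera (adjusted p = 0.138), with a median log2 change of -0.03 and a mean of 0.16.

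In the fixed lists of other blood-derived cells, few genes passed. In the macrophage list, Cd68, a lysosomal glycoprotein of macrophages and osteoclasts, rose from 38.3 ± 2.18 to 76.3 ± 5.995 FPKM (SD, n = 3 each), and Csf1r, the receptor of Csf1 on both cell types, from 37.0 ± 2.51 to 55.0 ± 3.49. They were the 2 of 11 members that rose, also when adjusted over the list alone, while Adgre1, C1qb and C1qc, which macrophages express, had ratios of 1.19, 1.12 and 1.18 and did not pass. The macrophage list was higher in camera with a preset correlation (median log2 change 0.16, adjusted p = 0.000235). Its adjusted p was 0.397 with an estimated correlation and 0.0682 in fry. The neutrophil list was higher too in camera with a preset correlation (median 0.42, adjusted p = 0.00811), with an adjusted p of 0.54 with an estimated correlation and 0.369 in fry. None of its 7 members passed over all genes, and 3 rose when adjusted over the list alone. Its mean log2 value was 3.63, 3.30 and 2.54 in the libraries labelled mutant against 2.68, 2.82 and 2.74 in controls, so library 3 lay below every control. S100a8, Itgam, Ngp and S100a9 had mean ratios of 1.66, 1.33, 2.74 and 1.48. Csf1r did not pass when any 1 library was left out (adjusted p up to 0.118 over all settings tried). Without library 1 labelled mutant the neutrophil list did not pass (adjusted p = 0.104), nor did it with no filter on low values (0.332).

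Bone-forming cells showed no shared direction. Ibsp, the bone sialoprotein gene of mineralizing osteoblasts, rose from 908 ± 66.8 to 1755 ± 260 FPKM (SD, n = 3 each), a log2 change of 0.94 ± 0.12 (SE; adjusted p = 0.0306, limma with Benjamini-Hochberg adjustment), as the 1 member of 22 to pass. That call too held only without library 2 labelled mutant among the fits lacking a library (adjusted p up to 0.128 over all settings tried). Spp1, the osteopontin gene, had 2185 ± 174 and 3299 ± 394 FPKM (SD, n = 3 each) and Col22a1 had 48.3 ± 0.24 and 70.6 ± 9.66, neither past the threshold. Bglap and Bglap2, the near-identical osteocalcin genes whose reads cannot be cleanly parted, were named after their values were seen, at 170 ± 83.1 and 64.8 ± 17.7 FPKM for Bglap and 110 ± 33.6 and 42.6 ± 13.7 FPKM for Bglap2 (SD, n = 3 each), also without passing. Adjusted over the list alone, 4 members rose and 2 fell. The list did not pass in camera (median log2 change 0.05, adjusted p = 0.106).

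Feedback genes of the Hedgehog pathway, which links hypertrophic cartilage to bone formation, were also higher. Ptch1, a Hedgehog receptor that the pathway itself induces, rose from 5.44 ± 0.26 to 9.28 ± 0.71 FPKM (SD, n = 3 each; log2 change 0.67 ± 0.08 SE, adjusted p = 0.0177 in limma with Benjamini-Hochberg adjustment), and Hhip, a Hedgehog-binding inhibitor induced in the same way, from 3.39 ± 0.42 to 7.17 ± 1.24. Boc, a Hedgehog co-receptor, had 38.8 ± 1.86 and 30.3 ± 2.296 FPKM (SD, n = 3 each) and did not pass over all genes. These were 2 rises among 12 members, and leaving out any 1 library ended both calls (adjusted p, over all settings tried, up to 0.0799 for Ptch1 and 0.146 for Hhip). Over the list alone, 2 rose and 3 fell, and camera gave an adjusted p of 0.562 (median log2 change 0.04). The list of matrix proteases likewise owed its 2 rises of 15 to Mmp9 and Mmp13, 2 of them also when adjusted over the list alone, while Adamts2, a procollagen protease, had 50.7 ± 0.82 and 43.0 ± 3.96 FPKM (SD, n = 3 each; adjusted p of the list 0.168 in camera, median 0.05).

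In the blood vessel list, 9 of 11 genes had higher values and 2 had lower values. Emcn, a sialomucin of vessel lining, rose from 29.4 ± 1.39 to 38.3 ± 0.22 FPKM (SD, n = 3 each), a log2 change of 0.37 ± 0.06 (SE; adjusted p = 0.0476, limma with Benjamini-Hochberg adjustment). It was the 1 member of 11 to pass, and 7 rose when adjusted over the list alone. Leaving out any 1 library ended the call for Emcn (adjusted p up to 0.192 over all settings tried). Flt1, Cdh5 and Pecam1 had ratios of 1.31, 1.16 and 1.11. The list was higher in camera with a preset correlation (median log2 change 0.19, adjusted p = 5.54e-05) and in fry (adjusted p = 0.0443), and its adjusted p was 0.183 with an estimated correlation.

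The BMP, suture, Wnt and FGF lists lay lower in camera with a preset correlation, with no member past the threshold over all genes. With an estimated correlation the adjusted p was 0.397 for BMP and 0.54 for each of the suture, Wnt and FGF lists. In fry it was 0.262 for BMP, 0.396 for suture, 0.396 for Wnt and 0.369 for FGF. In the BMP list of 22 genes, 19 had lower values (median log2 change -0.22, camera adjusted p = 0.000235), with Id1, a direct BMP target, at 95.3 ± 10.7 and 65.6 ± 6.53 FPKM (SD, n = 3 each), and the BMP antagonist genes Chrd and Chrdl1 at ratios of 0.815 and 1.41. In the suture list of 26 genes, 20 had lower values (median -0.14, adjusted p = 0.000791), among them Msx2 and Alx4, transcription factors of skull growth, at ratios of 0.668 and 0.795, and Axin2, a Wnt feedback gene that marks suture cells, at 0.682. In the Wnt list of 29 genes, 19 had lower values (median -0.13, adjusted p = 0.0361), with Lgr5 and Nkd1 at ratios of 0.589 and 0.637. In the FGF list of 15 genes, 10 had lower values (median -0.11, adjusted p = 0.0134), with Fgf1, Spry2 and Fgfrl1 at ratios of 0.721, 0.743 and 0.802. Adjusted over the list alone, 1 BMP gene rose and 3 fell, 2 Wnt genes rose and 6 fell, and the suture and FGF lists had 0 either way. Leaving out library 2 labelled mutant ended the suture call (adjusted p = 0.0536), the FGF call (0.0534) and the Wnt call (0.204), and leaving out control 2 ended the FGF call (0.173) and the Wnt call (0.121). The Wnt list also failed without control 3 (0.0561) or library 1 labelled mutant (0.0926), with no filter on low values (0.064) and with the filter at 5 FPKM (0.178), and the FGF list with array weights (0.0554).

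The list built on the receptor pathway itself was marginally higher (median log2 change 0.04 over 24 genes, camera adjusted p = 0.0426). Its adjusted p was 0.397 with an estimated correlation and 0.163 in fry. None of its members passed over all genes, and 2 rose when adjusted over the list alone, Pth1r itself and Pthlh. Of the 24 members, 16 had a higher value and 8 a lower one. Pthlh, the gene of parathyroid hormone-related protein, had 2.48 ± 0.61 and 4.40 ± 0.50 FPKM (SD, n = 3 each), and the arrestin gene Arrb2 had 14.2 ± 0.70 and 16.5 ± 1.23. This list did not pass without control 1 (adjusted p = 0.102), control 3 (0.108) or library 2 labelled mutant (0.157), nor with the filter at 5 FPKM (0.211), array weights (0.0588) or a sex term (0.133).

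**Figure D2:**
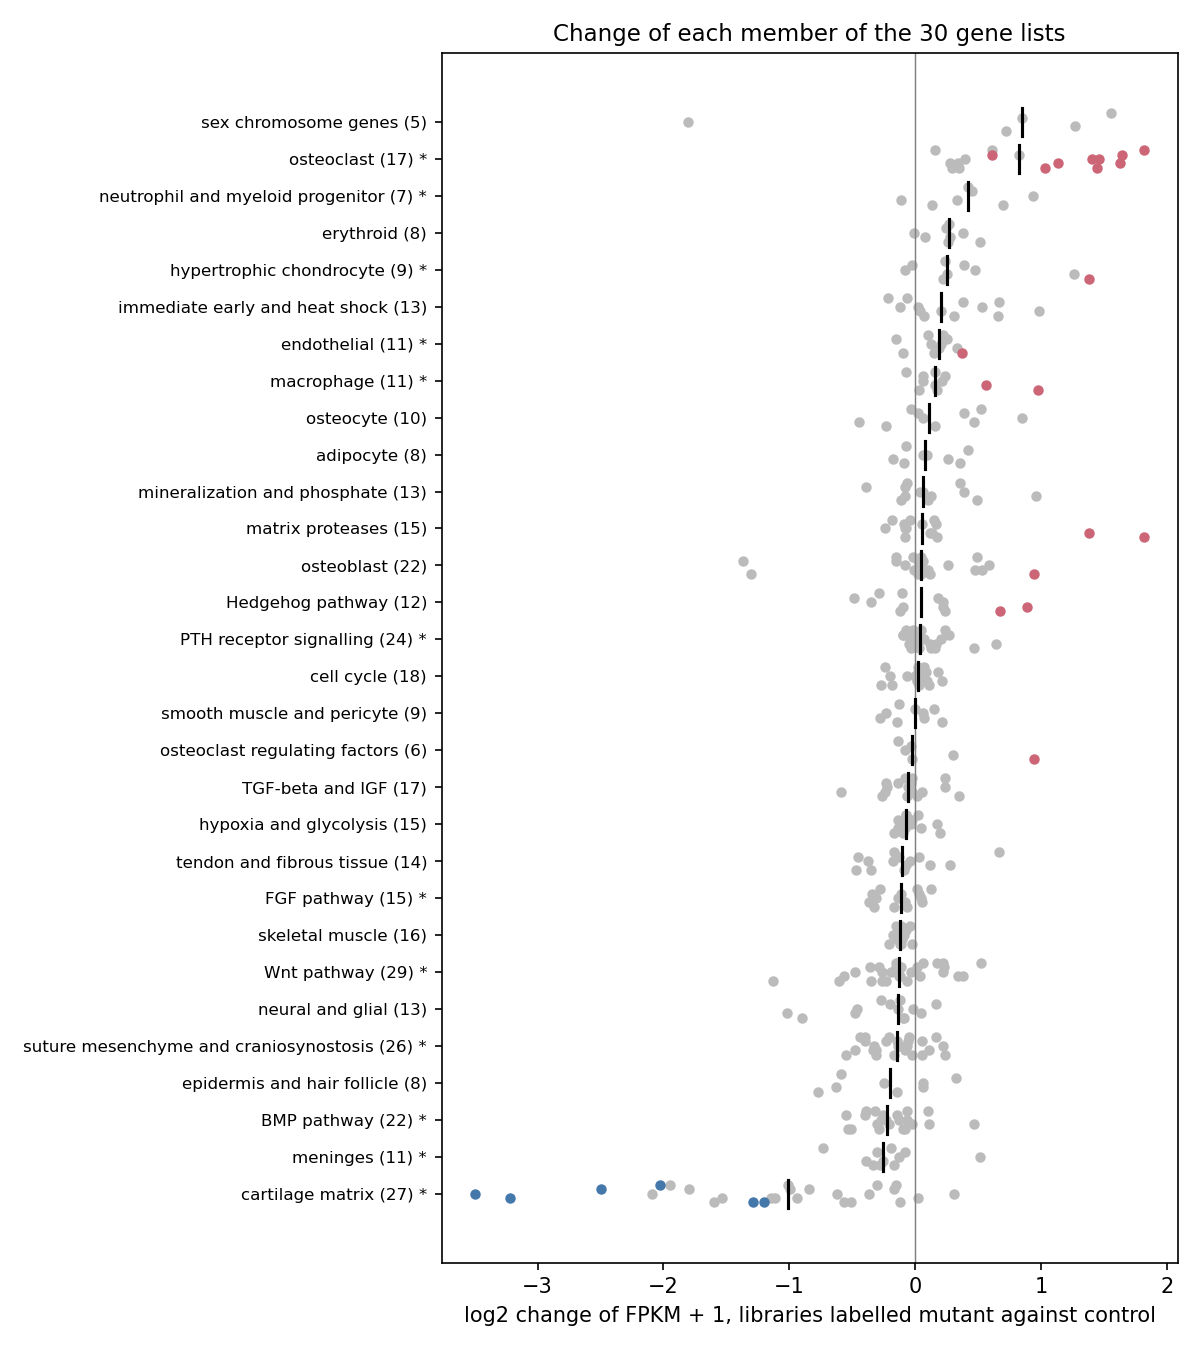
Log2 change of FPKM + 1 between the libraries labelled mutant and control (horizontal axis) for each measured member (points) of the 30 gene lists (rows, number of members in brackets, * camera adjusted p under 0.05 with a preset correlation). Red points rose and blue points fell at an adjusted p of 0.05 over all genes, grey points did not pass, and black bars are medians, from -1.01 for cartilage matrix to 0.83 for osteoclasts among the lists that passed.

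Other tissues in the dissection varied from library to library. Meningeal genes were lower in camera with a preset correlation (median log2 change -0.25 over 11 genes, adjusted p = 0.0151). The adjusted p of this list was 0.54 with an estimated correlation and 0.396 in fry, with 0 members past the threshold over all genes or adjusted over the list alone. Control 1 had the lowest mean log2 value of all 6 libraries in this list, 4.78, and 30.9 FPKM of Ptgds against 432 and 422 in controls 2 and 3. Zic1, Foxd1, Aldh1a2 and Igf2 had ratios of 0.794, 0.755, 1.40 and 0.947. The meningeal list did not pass without control 2 (adjusted p = 0.108), control 3 (0.108) or library 2 labelled mutant (0.0703). Red cell genes did not pass (adjusted p = 0.312, median 0.27, 0 of 8 members over all genes or the list alone), but Hba-a1 ran at 11515, 9783 and 2584 FPKM in libraries 1, 2 and 3 labelled mutant and between 4607 and 6667 in controls. Alas2, Car2 and Hbb-b2 had mean ratios of 1.54, 1.21 and 1.14, and the globin genes share reads among near-identical copies. The log2 change of Hbb-b2 was -0.0073, of the opposite sign to its ratio of means. Muscle genes did not pass either (adjusted p = 0.177, median -0.12, 0 of 16 members both ways), with Acta1 at 6008 ± 1593 and 5179 ± 1263 FPKM (SD, n = 3 each) and ratios of 0.90, 0.886 and 0.944 for Des, Tnnt3 and Mylpf. Neural and glial genes did not pass (adjusted p = 0.083, median -0.13, 0 of 13 members both ways), and Tubb3 ran at 10.5, 59.2 and 7.63 FPKM in the libraries labelled mutant, so its log2 change (-0.47) and its ratio of means (1.06) differ in sign. Sox10 and Gap43 had ratios of 0.418 and 0.894. Single libraries set the means of Snap25, at 4.82, 9.48 and 6.79 FPKM in controls and 7.90, 3.64 and 0.387 in the libraries labelled mutant, and of Nefl, at 1.36, 1.13 and 2.60 FPKM against 0.777, 2.01 and 0.289.

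Genes that respond within minutes to the handling of tissue did not pass as a list (median 0.21, adjusted p = 0.083), with 0 of 13 members past the threshold over all genes and 1 that rose over the list alone. Zfp36, Fos, Junb, Egr1 and Jun had ratios of 1.61, 1.96, 1.45, 1.496 and 0.987, with a log2 change of 0.02 for Jun. Animals of both sexes were present in each group: Xist was at 42.7, 42.5 and 43.0 FPKM in controls 1 and 3 and library 1 labelled mutant, and Ddx3y at 12.4, 12.6 and 12.8 FPKM in control 2 and libraries 2 and 3 labelled mutant. The sex chromosome list, with Eif2s3y and Uty, did not pass (adjusted p = 0.431, median 0.85, 0 of 5 members both ways).

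**Figure D3:**
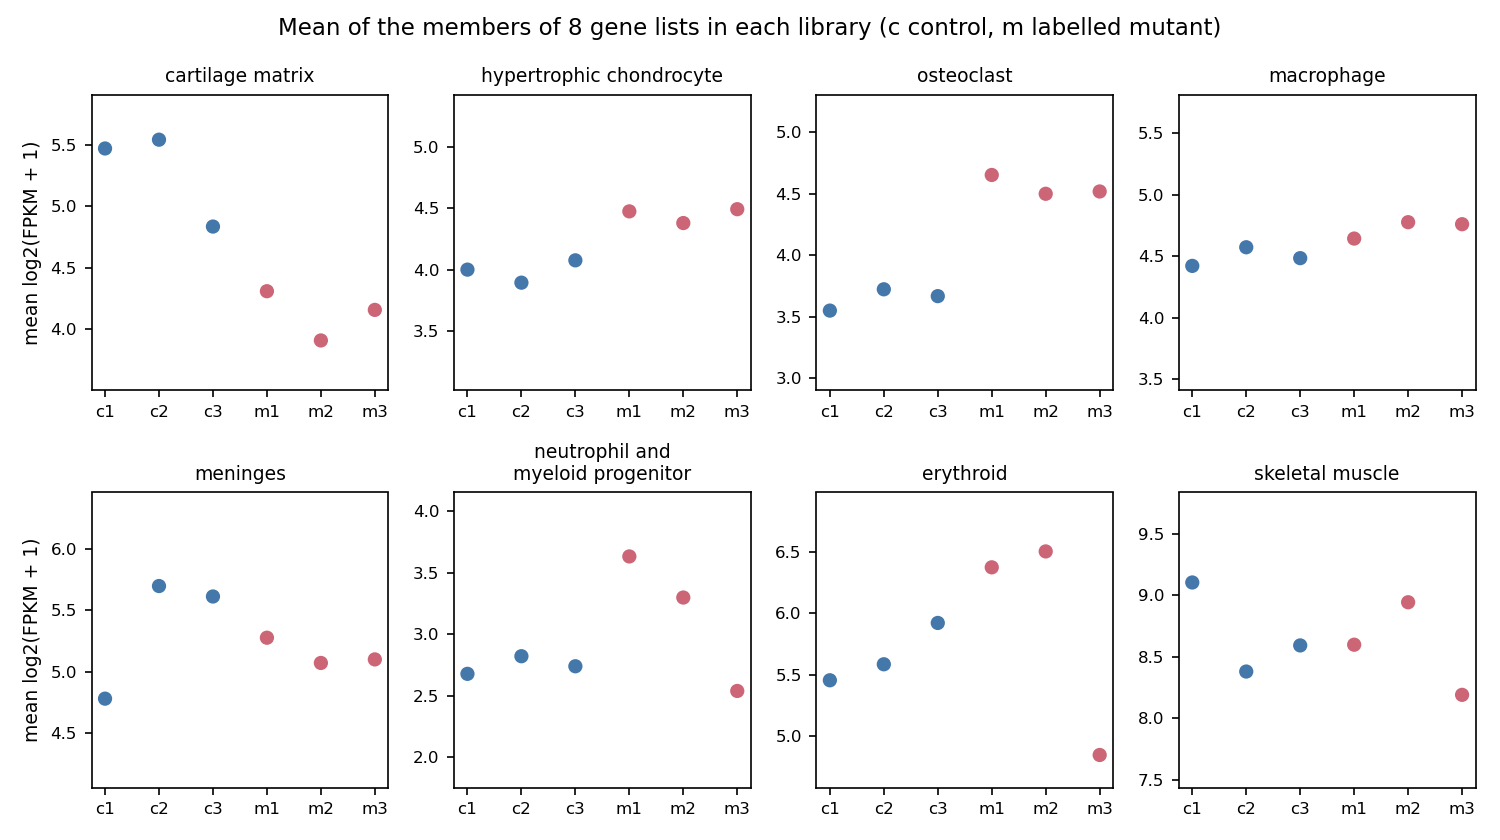
Mean log2(FPKM + 1) over the measured members of 8 gene lists in each library (points), with controls c1 to c3 in blue and libraries m1 to m3 labelled mutant in red; each vertical axis spans the same log2 range. The groups do not overlap for cartilage matrix, hypertrophic chondrocyte, osteoclast and macrophage genes, while erythroid and neutrophil genes are lowest in m3 and meningeal genes are lowest in c1.

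The remaining lists did not pass in camera and had no member past the threshold over all genes. Their median log2 changes were 0.11 for osteocyte, -0.06 for TGF-beta and IGF, 0.06 for mineralization and phosphate, -0.11 for tendon, 0.08 for fat cell, 0.02 for cell cycle, -0.07 for hypoxia, -0.0024 for smooth muscle and -0.20 for skin genes. Adjusted over the list alone, 3 osteocyte genes rose and 1 fell, 1 TGF-beta and IGF gene rose and 1 fell, 2 mineralization genes rose, 1 smooth muscle gene rose and 2 fell, and 1 skin gene fell, with 0 either way in the tendon, fat cell, cell cycle and hypoxia lists. The B cell list had 3 measured members, too few for the test, with a median of 0.06. In the cell cycle list the median lay above 0 and the mean and test below it.

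Among the largest changes outside the lists, the metallothionein gene Mt3 rose 3.36-fold to 53.6 ± 6.59 FPKM (SD, n = 3). Mfi2, the older name of the melanotransferrin gene Meltf, fell from 8.46 ± 3.08 to 1.197 ± 0.22 FPKM (SD, n = 3 each), the secreted protein gene Wfdc2 from 18.1 ± 5.17 to 5.22 ± 0.83, the ubiquitin ligase subunit gene Fbxo2 from 1.82 ± 0.25 to 0.50 ± 0.16, and the carboxypeptidase-like gene Cpxm2, whose span overlaps Fgfr2 on the same strand, from 27.5 ± 0.90 to 16.8 ± 1.89. Among the fits lacking a library, Mt3 passed in 2, and Mfi2, Wfdc2 and Cpxm2 each passed in 1. Fbxo2 passed in no such fit in which it was tested. The remaining fall, named after its values were seen, was that of the Wnt receptor gene Fzd1, from 31.0 ± 1.75 to 21.2 ± 1.503 FPKM (SD, n = 3 each; adjusted p = 0.0379 in limma with Benjamini-Hochberg adjustment). Leaving out any 1 library ended this call (adjusted p up to 0.151 over all settings tried). A pair of the largest rises are uncertain. Bcl2a1b, which shares reads with near-identical Bcl2a1 copies, rose from 0.615 ± 0.27 to 3.84 ± 1.21 FPKM (SD, n = 3 each), and the short RNA gene Mir8094, which lies within the gene Ddx39b on the same strand, from 108 ± 9.13 to 502 ± 216.

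On GRCm38, in the GENCODE annotation, Matn1 lies at 130944385 to 130955475 of chromosome 4, Col9a3 at 180597790 to 180622189 of chromosome 2, Cilp2 at 69880369 to 69887687 of chromosome 8 and Ucma at 4976122 to 4985748 of chromosome 2. Acp5 lies at 22126727 to 22135711 and Mmp13 at 7272514 to 7283331 of chromosome 9, Ctsk at 95499256 to 95509362 of chromosome 3, Mmp9 at 164940780 to 164955850 of chromosome 2 and Atp6v0d2 at 19876841 to 19922605 of chromosome 4. Tnfsf11 lies at 78277445 to 78308043 of chromosome 14, Ptch1 at 63508328 to 63573598 of chromosome 13 and Ibsp at 104299171 to 104311469 of chromosome 5. All of these are protein-coding genes.

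The p values of single genes measure the spread between 3 libraries per group, whose origin from separate animals is not stated in the labels beyond a number. Those of camera with a preset correlation of 0.01 also rest on the spread between genes, taken as nearly independent. The estimated correlation was 0.649 for cartilage matrix and 0.176 for osteoclast, so their very small p values do not measure the spread between libraries. The 69 rises became 31, 33 and 32 without control 1, 2 or 3 and 15, 34 and 30 without library 1, 2 or 3 labelled mutant, the 11 falls became 8, 3, 12, 1, 4 and 5 in the same order, and 9 of the 30 named genes past the threshold stayed past it in all 6 fits (Acp5, Atp6v0d2, Ctsk, Dcstamp, Itgb3, Mmp9, Mmp13, Cd68 and Cilp2).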

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

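Among the alternatives that kept all libraries, the largest shifts in the counts of genes came with array weights, a sex term, the replicate number as a block and no filter on low values. Against 69 rises and 11 falls, array weights gave 152 and 31, the sex term 41 and 2, no filter 44 and 6, and leaving out short RNA genes 82 and 17. The sex term and the fit without short RNA genes were chosen after seeing the data. With the replicate number as a block, 23 genes rose and 2 fell. The labels do not say whether the numbers pair the libraries. Deviations from the group means correlated at 0.016, -0.071 and 0.015 between libraries with number 1, 2 and 3, so no pairing was seen. If there is none, that block spends degrees of freedom on an arbitrary pairing. Testing more genes without the filter raises the adjustment, and for the other shifts the cause was not tested. Pseudocount, median-of-ratios scaling, quantile normalization, the filter at 5 FPKM, eBayes without trend and robust eBayes gave between 57 and 82 rises and between 9 and 11 falls. The 6 cartilage matrix genes that fell became 2 with robust eBayes, 1 with the sex term, 1 with the replicate number as a block and 3 with no filter. Leaving out 1 library gave between 15 and 34 rises and between 1 and 12 falls, with fewer samples in each fit. Of the 80 genes past the threshold, 15 passed under every alternative in which they were tested and 0 changed direction. Of these 15, 2 (Dcstamp and Tm4sf19) fall below the filter at 5 FPKM and were not tested there.

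The 6 lists higher and 6 lower in camera became 0 and 0 with an estimated correlation and 3 and 0 with fry, which tests a different question, and the cause was not tested. Every other alternative gave between 5 and 8 lists higher and between 4 and 8 lower. Robust eBayes gave no list result, and the planned count tool was not run, because the values are not counts. The osteoclast, cartilage matrix, hypertrophic chondrocyte, macrophage, endothelial and BMP lists passed in camera with the preset correlation under all 16 alternatives that refit the genes. Pth1r stayed higher throughout, and passed the threshold with array weights alone (log2 change 0.40, adjusted p = 0.0458, range over the alternatives 0.0458 to 0.201), for which the cause was not tested.

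Several values that had not passed changed sign, and for these the cause was not tested. With the sex term the log2 change was 0.0079 for Il34, 0.16 for Hbb-b2 and -0.075 for Jun, and the median was -0.00395 for the mineralization list and 0.00056 for the smooth muscle list. The same term left Xist at 0.0042 and Eif2s3y at -0.048, as it removes the sex difference by construction. With array weights Hbb-b2 was at 0.068, the osteoblast list at -0.049 and the hypoxia list at 0.0039. The Hedgehog list was at -0.10 with no filter and at -0.10 with the filter at 5 FPKM.

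Leaving out 1 library at a time moved the log2 change of Il34 from -0.17 to 0.041, Des from -0.29 to 0.044, Tnnt3 from -0.38 to 0.044, Mylpf from -0.28 to 0.11, Car2 from -0.041 to 0.53, Hba-a1 from -0.13 to 0.94, Hbb-b2 from -0.41 to 0.58, Tubb3 from -1.34 to 0.062, Ptgds from -1.53 to 0.35 and Jun from -0.10 to 0.27. List medians ran from -0.077 to 0.12 for osteoblast, -0.039 to 0.18 for osteoclast regulating factors, -0.016 to 0.11 for Hedgehog, -0.036 to 0.11 for matrix proteases, -0.047 to 0.22 for fat cell, -0.027 to 0.10 for cell cycle, -0.14 to 0.061 for hypoxia, -0.31 to 0.094 for muscle, -0.00483 to 0.73 for erythroid, -0.048 to 0.018 for smooth muscle and -0.46 to 0.062 for neural genes. The cause was not tested, and none of these results had passed in the full comparison.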

Other observations

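The tests on the amount and kind of cartilage, on blood and immune cells, and on the deleted part, osteoblast share and exchanged labels for Pth1r were chosen only after the result was seen. Outside the fixed lists, several genes known from osteoclasts rose in the libraries labelled mutant, and they are named here after their values were seen. Slc9b2, a sodium and proton exchanger induced in osteoclasts, rose from 7.87 ± 0.49 to 19.98 ± 0.52 FPKM (SD, n = 3 each), Slc37a2, a sugar phosphate transporter, from 8.83 ± 0.72 to 23.6 ± 0.37, and Snx10, a sorting protein needed for the ruffled border, from 8.72 ± 0.48 to 19.6 ± 1.67. Tm4sf19 rose 3.495-fold and Rac2, a small GTPase of blood-derived cells, 2.01-fold. Gpr137b and its pseudogene Gpr137b-ps rose 1.97-fold and 2.09-fold and may share reads, so neither is certain. All of these had an adjusted p of 0.00872 or less in limma with Benjamini-Hochberg adjustment.

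Lists of proton pump subunits and lysosomal proteins were written after the osteoclast result was seen. Of 15 pump genes 4 rose and 14 had a higher value (median log2 change 0.27), and of 19 lysosomal genes 3 rose and 15 had a higher value (median 0.16). The 27 members that had not been seen among the changed genes had a median of 0.16, with 22 higher, and fry gave an unadjusted rotation p of 0.000139 for them as a set. That is consistent with the acid-secreting machinery rising with the osteoclast genes, though macrophages also express lysosomal genes.

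Cartilage matrix genes were lower while the hypertrophic list, with 1 of 9 members past the threshold, was higher in camera with a preset correlation. With an estimated correlation neither list passed (adjusted p = 0.397 and 0.183), and in fry only the hypertrophic list did (adjusted p = 0.0682 and 0.0177). Less of every kind of cartilage in the tissue would lower Col10a1 too, whose log2 change was 1.26 ± 0.25 (SE). That gene did not pass over all genes (adjusted p = 0.109 in limma with Benjamini-Hochberg adjustment), and 1 gene alone cannot decide. As a set, 7 of the 9 hypertrophic members had a higher value and 2 a lower one. The list's mean log2 value ran from 3.89 to 4.08 in controls and from 4.38 to 4.49 in the libraries labelled mutant. These values argue against an equal loss of every kind of cartilage, though Mmp13 is also made in bone. Sex is argued against, as the median of the cartilage matrix list was -1.03 with a sex term. With median-of-ratios scaling it was -1.01, but the scaling factors ran only from 0.999 to 1.01 over the libraries. Such factors could hardly move any value, so that setting alone cannot decide on library scaling. A factor shared by a whole library moves all its genes together. The median log2 change of all tested genes was 0.0015, and the osteoclast list, with a median of 0.83, went the other way. These values argue against library scaling as the source of the lower cartilage matrix values. Less of a cartilage without hypertrophic cells could give the same values, and it stays open, since the highest control value of Matn1 was 2.75 times the lowest and the amount dissected was not given in the sources used here. A change in the cartilage itself stays open as well.

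Osteoclast genes were higher as a set in camera with a preset correlation, but not with an estimated correlation (adjusted p = 0.104). The list median was 0.93 with a sex term, which argues against sex as the whole source. It was 0.83 with median-of-ratios scaling, whose factors of 0.999 to 1.01 could hardly move it, so that setting alone cannot decide on library scaling. The median log2 change was 0.0015 over all tested genes and -1.01 in the cartilage matrix list. A factor shared by a whole library moves all its genes together, so these values argue against library scaling here too. More blood and immune cells of every kind is argued against by a gap of 0.60 between the median of 17 osteoclast genes (0.83) and that of 28 other blood and immune genes of the lists (0.22, SD 0.28; permutation p = 0.00024 over genes, which are not independent replicates). Outside the lists, Tyrobp and Laptm5, genes of blood-derived cells named after their values were seen, rose 1.71-fold and 1.56-fold. Their adjusted p was 0.00872 and 0.00664 in limma with Benjamini-Hochberg adjustment, and neither passed without library 1 labelled mutant. A rise of some blood-derived cells beyond osteoclasts therefore stays open. More osteoclasts, or more osteoclast transcripts per osteoclast, may each explain the rise of the osteoclast list, and neither was tested.

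Pth1r was higher, not lower, in the libraries labelled mutant. A deleted part with the rest of the transcript unchanged could leave the value of the whole gene near that of controls, and it stays open. The lowest value labelled mutant was 1.22 times the highest control value, but the difference did not pass its test and the comparison takes the labels as right. A larger share of osteoblasts could raise the gene and stays open, as the osteoblast list had a median of 0.047 with members that went both ways. Exchanged group labels cannot be told apart from a real rise, because all 3 libraries labelled mutant lay above all controls and no other measure of the genotype is in the files.

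The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 80 genes and the highest other split 6, so 1 of the 10 reached 80. At an unadjusted limma p under 0.05 the gap was smaller, with 1388 genes in the real split. The highest other split, control 1 with libraries 1 and 2 labelled mutant, gave 1176. The real split gave 12 lists and the highest other split 14, and 4 of the 10 reached 12.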
